A study of Rattus norvegicus with 21 samples.

How the data were processed

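Islets of Lewis rats were profiled by sequencing of polyadenylated RNA in 21 libraries, 10 from sham-operated animals and 11 from animals with partial pancreatectomy, all at 4 weeks. Groups, animal numbers and BG values were taken from the sample titles and characteristics, and every count column carried the title of 1 sample. The titles and characteristics give no sequencing batch or date.

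Per the submitters' processing notes, FastQC, Subread, featureCounts and limma were used, with no versions. The aligner settings, strand setting of the counting and genome build are not given in the sources used here. The deposited counts are whole numbers of reads per gene name in featureCounts layout, per the file headers, with no normalization, and the deposited table also gives a gene length in base pairs, which was not used. In the authors' deposited table of the comparison, per the file headers, the log2 fold change, the fold change as a linear ratio, the mean log2 expression and the p-value with its adjusted p are given per gene. The fold change in the authors' table equals 2 to the power of its log2 fold change. The library kit was directional, per the labels, but without the strand setting reads of overlapping antisense genes may not be told apart. Of the gene names, 173 span more than 1 chromosome or scaffold and 2 are listed on 2 rows; these, and families with near-identical copies such as Prss, RT1 and the Ins1 and Ins2 pair, have uncertain counts.

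From the counts, edgeR 4.0.16 in R 4.3.3 computed TMM factors, kept genes by filterByExpr (minimum count 10, minimum total 15) with the group, and fitted robust quasi-likelihood models. The slope fit used the 11 PX libraries with BG per 10 units. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic. CPM are TMM-scaled. Log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at least 5 measured members, and again with an estimated correlation and with fry, whose p-value tests whether members move one way on balance. There were 31 lists of 561 distinct genes. Named genes were the 8 highest and 8 lowest log2 fold changes among called genes of at least 10 mean CPM with a gene symbol, 14 islet genes always named, and up to 4 members of each list by p; some genes that this rule names are not reported here. A score is the mean log2 CPM of a list's measured members. Group differences of single values used permutation tests of means with 100000 resamples in scipy 1.17.1, or exact enumeration under 10 values, with adjustment over 12 library measures.

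Lists, tests, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were DESeq2 size factors, library totals only, upper-quartile factors, totals without the 20 most abundant genes, no filter, CPM above 1 in 10 libraries, DESeq2 1.42.0, limma voom with and without quality weights, the acinar score or 4 surrogate variables (sva 3.50.0) as covariates, the 8 PX animals of BG 121 or less, and each library left out. Leaving out PX 44, PX 65 and sham 46, the macrophage and mesenchymal scores as covariates and the libraries with overlapping acinar scores were chosen after seeing the data, as was a comparison of each library with the range of the PX libraries on genes whose groups do not overlap, sham 46 set aside.

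The fits were tested on simulated counts drawn from the real means, library sizes and dispersions. For PX against sham over 13012 genes, 80.2% of genes changed by 1 on the log2 scale and 28.0% of those changed by 0.5 were recovered, with 1.87% false calls. For the BG slope over 13121 genes, 70.0% of slopes of 0.25 and 89.0% of slopes of 0.5 were recovered, with 4.79% false calls. Simulated genes were drawn independently, without the shared variation of the real libraries, so these rates may not hold for the real counts. There, 1 shuffled order of BG called 1372 genes. Pairs of libraries within a group were compared by a chi-square of counts per degree of freedom. The lowest value was 4.37, for sham 73 and 74, and the next was 8.43, for sham 47 and 48. Both lie above the value of 1 for sampling noise, so no pair was counted as 1 library sequenced again. The comparison cannot tell libraries prepared from the same animal from libraries of separate animals.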

Results

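RNA was sequenced from islets of Langerhans, the hormone-secreting cell clusters of the pancreas, of Lewis rats 4 weeks after surgery. In the PX group, 90% of the pancreas had been removed (partial pancreatectomy, an operation that leaves a small remnant to meet the demand for insulin), and the sham group was sham-operated. There were 11 PX and 10 sham libraries, and each sample title carries its own animal number, by which the libraries are named here. Nothing in the labels beyond that number states that the libraries came from separate animals, and the p-values measure the spread between these libraries. The total count per library ran from 4001908 to 13187959 over 28914 gene names. The totals of the groups differed by less than the spread between libraries (permutation test, adjusted p = 0.40). The acinar score, the mean log2 CPM (counts per library total scaled by its TMM factor) of 25 markers of the enzyme-secreting exocrine cells, was higher in PX, at 11.1 ± 1.19 (SD, n = 11) against 9.34 ± 1.98 (SD, n = 10), with an adjusted permutation p = 0.040 over 12 library measures. Acinar markers took 20% ± 12.3 of the counts in PX and 10.8% ± 9.34 in sham (SD, n = 11 and n = 10), and 49.7% in PX 65. The difference in this share did not pass (permutation test, adjusted p = 0.085). Within the sham group this share went with the animal number, from 0.645% to 6.12% in sham 21, 22, 24, 73 and 74 and from 13.1% to 23.7% in sham 46 to 50. In PX it was 6.27% to 16.7% in PX 36 to 44 and 17.5% to 49.7% in PX 57 to 70; each such run of animal numbers holds libraries of 1 group only, so the groups could not be compared within a run. The percent of counts on mitochondrial genes was lower in PX, at 2.91% ± 1.30 (SD, n = 11) against 4.34% ± 1.28 (SD, n = 10), and more genes had a count, 17180 ± 393 against 16830 ± 311 (permutation tests, adjusted p = 0.040 and 0.048).

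**Figure D1:**
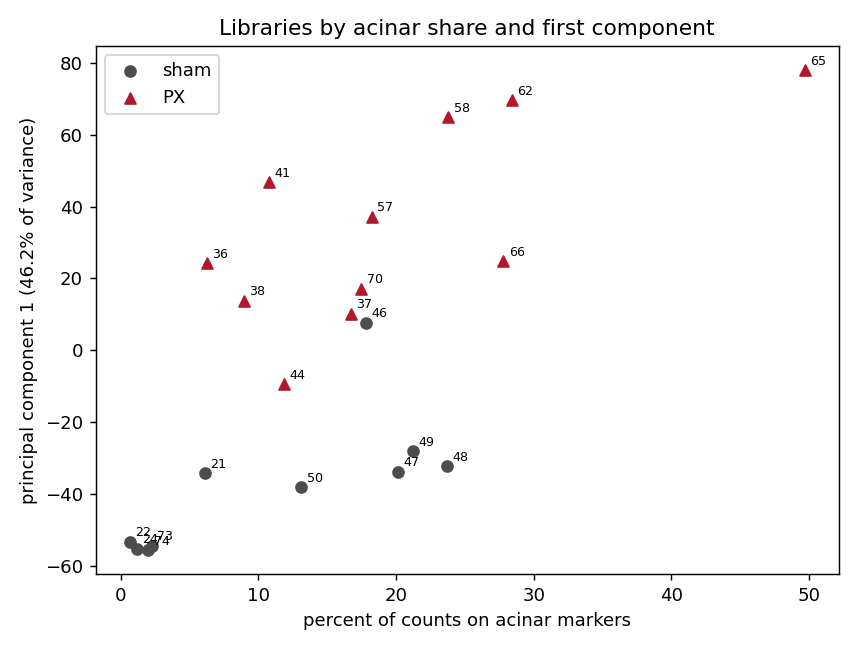
Each point is 1 library, with its animal number, sham as circles and PX as triangles. The horizontal axis is the percent of counts on acinar markers and the vertical axis is principal component 1 of log2 CPM, which held 46.2% of the variance; sham 46 at 7.65 and PX 44 at -9.45 lay nearest to the other group.

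The labels give an average BG before sacrifice for each animal, without a unit. It was 124 ± 23.1 in PX (SD, n = 11) and 94.7 ± 6.001 in sham (SD, n = 10), a difference of 29.0 (two-sided permutation test, p = 4e-05). PX animals ranged from 101 to 174 and sham animals from 82 to 104. With the 8 PX animals of 121 or less, the PX mean was 111 ± 6.46 (SD, n = 8) and the difference 16.7 (two-sided exact permutation test, p = 9.1e-05).

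The comparison of PX with sham asks how islet gene expression differs after the operation that raises the load on the remaining islets. Among called genes with a symbol and at least 10 mean CPM, genes of macrophages, inflammation and the extracellular matrix had the highest fold changes. Mmp12, an elastase of macrophages, rose 86.3-fold, from 1.38 ± 0.874 CPM in sham (SD, n = 10) to 124 ± 135 CPM in PX (SD, n = 11), a log2 fold change of 6.43 ± 0.71 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.1e-06). Among islet hormones, Sst, which encodes somatostatin, fell by 1.21 ± 0.17 on the log2 scale, from 992 ± 259 to 430 ± 119 CPM (edgeR, Benjamini-Hochberg adjusted p = 1.3e-05). Ins1 and Ins2, the insulin genes, had log2 fold changes of -0.12 ± 0.22 and 0.09 ± 0.26, within the spread between libraries. Of 21 genes normally kept low in beta cells 19 rose, among them Ldha, lactate dehydrogenase A, by 6.50-fold, in the libraries where macrophage and mesenchymal markers rose; the call of this list ended with an estimated correlation (camera adjusted p = 0.0985). With the macrophage and mesenchymal scores as covariates, chosen after seeing the data, 0 of 125 called named genes kept their call, and the log2 fold changes of Mmp12, Sst and Ldha were 3.10, -0.90 and -0.73 (edgeR adjusted p = 0.0912, 0.236 and 0.341). These scores explain most of the variance of group (R squared 0.769), so most calls would be lost in this fit whatever their source. Some named genes, Csf1r and Col3a1 among them, are also members of these scores, as are 4 of 24 matrix and 1 of 21 disallowed genes. For such members the loss is largely built in. A lost or turned result with these covariates, here and below, cannot tell RNA of these cells from a change in other cells.

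The other 7 genes of the highest fold changes among those with a mean of at least 10 CPM were Gpnmb, C3, Spp1, Lgals3, Il1rn, Postn and Vcan, with log2 fold changes from 4.98 to 6.40. Gpnmb and Lgals3 are known from activated macrophages, C3 is a complement component, and Postn and Vcan encode matrix proteins. In each of these 8 genes all 11 PX libraries lay above every sham library. Of the 15 measured macrophage markers 15 rose, and 15 passed when adjusted over the list alone. Their median log2 fold change was 2.74, with Csf1r, a growth factor receptor of the lineage, at 14.4 ± 6.03 CPM in sham and 77.5 ± 45.04 CPM in PX. Camera gave the list an adjusted p = 1.0e-16, and adjusted p = 0.0985 with an estimated correlation. All 24 matrix genes rose, as they did when adjusted over the list alone, with a median log2 fold change of 1.92. Examples were Sparc at 1.33 ± 0.14 and Mmp14 at 2.58 ± 0.29. The camera adjusted p was 3.3e-20, and adjusted p = 0.0985 with an estimated correlation. Of 15 antigen presentation genes 13 rose and 2 were not called, with the same counts adjusted over the list alone. Cd74, the class II invariant chain, rose 7.27-fold, and RT1-Da rose 10.3-fold (camera adjusted p = 3.5e-12, and adjusted p = 0.0985 with an estimated correlation). Reads of RT1 genes can be shared between near-identical copies, so their split is uncertain. Of 18 interferon-stimulated genes 12 rose and 6 were not called, 13 rose when adjusted over the list alone, and Gbp2 rose 3.66-fold (camera adjusted p = 1.9e-05, and adjusted p = 0.103 with an estimated correlation). Interferon rises numbered 4 with library totals only and 6 with the acinar score as a covariate. Of 16 NF-kB targets and cytokines 9 rose and 7 were not called, 12 rose when adjusted over the list alone, and Lcn2 rose 19.02-fold (camera adjusted p = 4.6e-09, and adjusted p = 0.0985 with an estimated correlation). With the macrophage and mesenchymal scores as covariates the mean of the interferon list turned to -0.23, with Psmb8 at -0.50 and Psmb9 at -0.42, and the interferon, matrix, antigen presentation and NF-kB lists were not called (camera adjusted p = 0.645, 0.238, 0.645 and 0.689). The NF-kB list then had a mean of 0.33 and a median of -0.031. In the 5 sham and 8 PX libraries of overlapping acinar scores, also chosen after seeing the data, 14 matrix and 3 interferon genes rose, and without PX 44 alone 14 NF-kB genes rose. Beside these immune and matrix groups the mesenchymal score was higher in PX, at 5.76 ± 0.624 (SD, n = 11) against 4.08 ± 0.498 (SD, n = 10), with an adjusted permutation p = 6e-05.

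**Figure D2:**
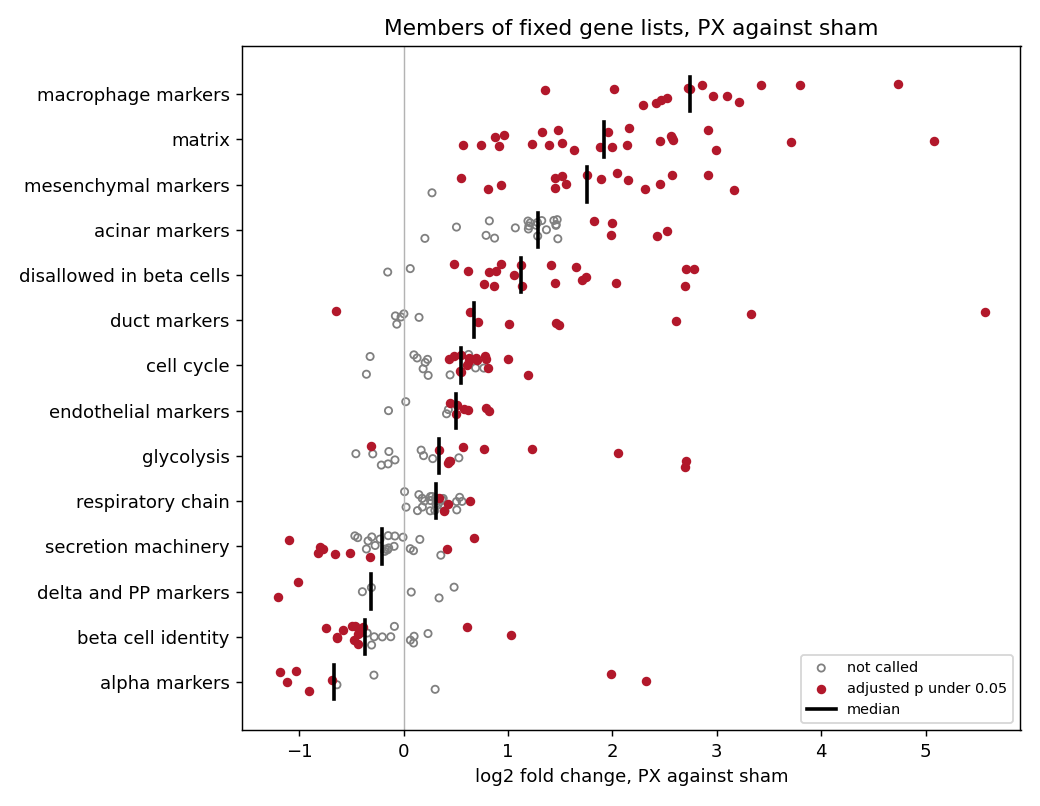
Each point is a measured member of a gene list fixed before the data were examined, placed by its log2 fold change of PX against sham on the horizontal axis; filled points have an edgeR adjusted p under 0.05, open points do not, and black bars are list medians. Among the lists shown, the medians ran from -0.66 for alpha cell markers to 2.74 for macrophage markers. The lymphocyte list, with 4 measured members and a median of 3.34, is not shown.

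Among beta cell identity genes more fell than rose. Of 24 measured members 11 fell, 2 rose and 11 were not called, and 13 fell and 2 rose when adjusted over the list alone; the median log2 fold change was -0.37. The camera adjusted p was 0.00923, and adjusted p = 0.347 with an estimated correlation. Leaving out 1 library gave 7 to 12 falls, with 7 without sham 21, sham 22, sham 74 or PX 41, and 1 to 2 rises. In the fits with 7 falls TMM scaled to sham 47, against PX 44 in the main setting. In the libraries of overlapping acinar scores 0 members were called (camera adjusted p = 0.0216). Falls included Pax6 by 0.64 ± 0.14, Rfx6 by 0.74 ± 0.17 and Nkx6-1 by 0.64 ± 0.19 on the log2 scale, all transcription factors of endocrine cells, and Abcc8, a subunit of the ATP-sensitive potassium channel, by 0.50 ± 0.11. Pdx1 fell by 0.44 ± 0.13 and Ucn3, urocortin 3 of mature beta cells, fell by 0.46 ± 0.16 (edgeR, Benjamini-Hochberg adjusted p = 0.0125 and 0.0330). Npy1r, a neuropeptide Y receptor, rose by 1.03 ± 0.19. Mafa, Slc2a2 and Gcg had log2 fold changes of -0.31 ± 0.18, -0.09 ± 0.17 and -0.28 ± 0.29, and Ppy of 0.34 ± 0.27, none of them called. Secretion machinery showed 7 falls and 2 rises among 28 members, with 19 not called, and 8 falls and 2 rises adjusted over the list alone (median -0.20; camera adjusted p = 0.0167, and adjusted p = 0.347 with an estimated correlation). The calcium channel genes Cacna1c, Cacna1a and Cacna1d fell by 0.82 ± 0.16, 0.80 ± 0.17 and 0.66 ± 0.15 on the log2 scale. The macrophage score was higher in PX beside these falls, at 4.27 ± 0.916 (SD, n = 11) against 1.77 ± 0.401 (SD, n = 10). With the macrophage and mesenchymal scores as covariates, chosen after seeing the data, the mean log2 fold change of the identity list turned to 0.34 (camera direction up, adjusted p = 0.0155) and that of the secretion list to 0.023 (adjusted p = 0.778). The log2 fold changes of Nkx6-1, Rfx6 and Ucn3 were then 0.064, 0.30 and 0.26, none of them called. The secretion call ended with the acinar score as a covariate (camera adjusted p = 0.135) and in the libraries of overlapping acinar scores (adjusted p = 0.169), where 1 member fell and 0 rose. The 8 most decreased genes of at least 10 CPM were Cabp7, Unc5c, Cntn3, Casr, Ndst4, Syt12, Tenm4 and Dnah2, with log2 fold changes from -1.69 to -1.38. Cabp7, a calcium-binding protein, fell by 1.69 ± 0.29, from 69.0 ± 19.7 to 21.3 ± 13.5 CPM, and Casr, the calcium-sensing receptor, fell by 1.43 ± 0.23.

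Of 21 disallowed genes, which beta cells normally keep low, 19 rose and 2 were not called, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.13. The camera adjusted p was 3.5e-12, and adjusted p = 0.0985 with an estimated correlation. Ldha rose from 3.46 ± 1.39 to 22.5 ± 20.4 CPM, a log2 fold change of 2.70 ± 0.44, and Mgst1, Hk2 and Rest had values of 2.78 ± 0.33, 2.69 ± 0.38 and 1.65 ± 0.22. Macrophage and mesenchymal markers rose in the same libraries, with medians of 2.74 and 1.76. With both scores as covariates the median of the disallowed genes turned to -0.045 and called members went from 19 to 0, with Ldha at -0.73 and Hk2 at -0.033, and neither this list nor the dedifferentiation list was called (camera adjusted p = 0.645 for each). In the libraries of overlapping acinar scores 10 disallowed and 2 dedifferentiation genes rose. Of 8 dedifferentiation markers 5 rose and 3 were not called, with 5 rises and 1 fall when adjusted over the list alone (median 0.85; camera adjusted p = 0.00346, and adjusted p = 0.0985 with an estimated correlation). Aldh1a3, an aldehyde dehydrogenase, rose by 1.91 ± 0.37 and Vim, the filament protein vimentin of mesenchymal cells, by 2.55 ± 0.25. Sham 46 had a higher Aldh1a3 level than the other sham libraries, at a log2 CPM of 4.63 against 2.73 for the next.

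**Figure D3:**
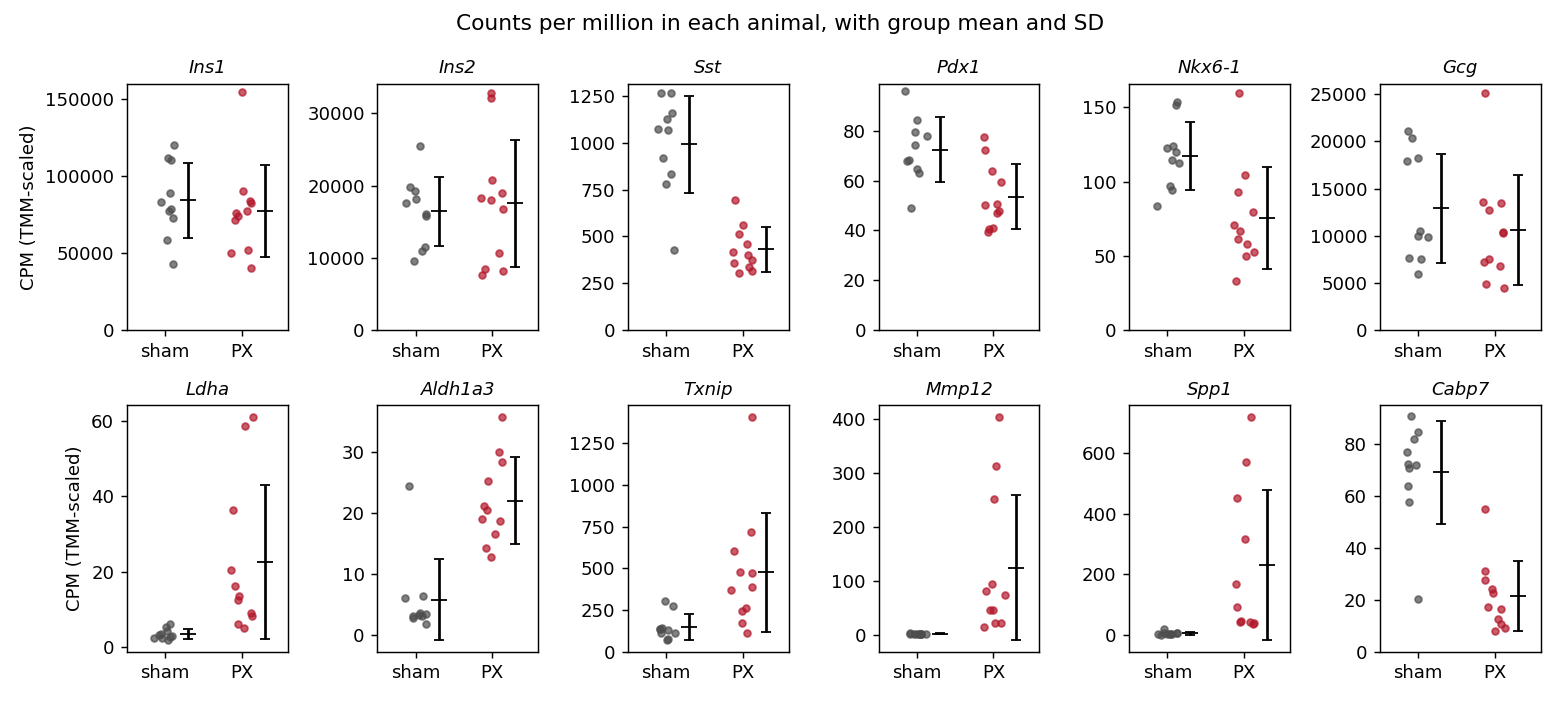
Each point is 1 library, and the vertical axes are TMM-scaled CPM on linear scales; black marks are group means with SD, for sham (n = 10) and PX (n = 11). Sst averaged 992 in sham and 430 in PX, and Ldha 3.46 and 22.5, while the Ins1 values of the groups overlapped.

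Of 21 glycolysis genes 10 rose, 1 fell and 10 were not called, and 11 rose and 1 fell adjusted over the list alone (median 0.34, camera adjusted p = 0.0160, and adjusted p = 0.307 with an estimated correlation). Glycolysis rises numbered 3 with library totals only, 2 with the acinar covariate, 6 without a filter and 13 with voom quality weights. Hk2 and Ldha, at 2.69 and 2.70, are also on the disallowed list. Respiratory chain subunits had 4 rises among 28 members and 0 when adjusted over the list alone, with a median of 0.31 (camera adjusted p = 5.3e-04, and adjusted p = 0.347 with an estimated correlation), beside the lower percent of counts on mitochondrial genes. These rises numbered 1 without PX 65, 2 without sham 48, PX 57 or PX 62, and 0 with library totals only or the acinar covariate. They numbered 7 without PX 38, 8 without sham 21, 10 without PX 36, 13 without PX 44, 14 without PX 37 and 16 without sham 46. In each of these fits with more rises TMM scaled to sham 47, against PX 44 in the main setting. With DESeq2 size factors and all libraries kept, 7 rose. The antioxidant list had 10 rises among 20 members, and 10 adjusted over the list alone, with Hmox1, heme oxygenase, rising 14.1-fold (camera adjusted p = 1.4e-04, and adjusted p = 0.0985 with an estimated correlation). Of 25 endoplasmic reticulum stress genes 7 rose and 18 were not called, and 7 rose adjusted over the list alone, among them Dnajb11 by 0.60 ± 0.12 and Atf3 by 1.54 ± 0.34 (camera adjusted p = 0.0160, and adjusted p = 0.340 with an estimated correlation). Of 15 immediate early genes 5 rose and 1, Nr4a1, fell, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0201, and adjusted p = 0.347 with an estimated correlation). Of 27 cell cycle genes 15 rose and 12 were not called, 18 rose adjusted over the list alone, and Mcm3 and Cdk1 rose by 1.20 ± 0.21 and 1.002 ± 0.17 (camera adjusted p = 2.4e-06, and adjusted p = 0.168 with an estimated correlation). Cell cycle rises numbered 2 with library totals only and 18 with voom quality weights. Macrophage markers were higher in the same PX libraries, with a median log2 fold change of 2.74. Acinar markers had a median of 1.28, but 5 of 25 were called and the acinar scores of the groups overlapped. With the macrophage and mesenchymal scores as covariates the mean log2 fold changes of the glycolysis, respiratory chain, immediate early and antioxidant lists turned to -0.33, -0.25, -0.24 and -0.078 (camera adjusted p = 0.0398, 0.0398, 0.238 and 0.955), while the antioxidant median was 0.019. The endoplasmic reticulum stress and cell cycle lists were then not called (adjusted p = 0.718 and 0.908). With the acinar score as a covariate the camera calls of the glycolysis, respiratory chain, endoplasmic reticulum stress, immediate early and secretion lists ended (adjusted p = 0.0829, 0.107, 0.138, 0.135 and 0.135). In the libraries of overlapping acinar scores 2 glycolysis, 1 antioxidant and 4 cell cycle genes rose, and 0 respiratory chain, endoplasmic reticulum stress and immediate early genes. Endoplasmic reticulum stress rises numbered 11 without PX 44 and 13 without sham 46, and immediate early rises 10 without PX 44. TMM scaled to sham 47 in these fits too. The immediate early call also ended without PX 37, sham 73 or sham 74 (adjusted p = 0.0586, 0.0562 and 0.0636), and with library totals only the endoplasmic reticulum stress list had a mean of -0.02 and an adjusted p = 0.183. Txnip, a glucose-induced inhibitor of thioredoxin, rose 3.19-fold, by 1.67 ± 0.37. Its list of ChREBP targets had 6 rises and 2 falls among 13 members, 6 and 3 adjusted over the list alone, and a camera adjusted p = 0.469. Senescence (5 rises and 2 falls of 11), heat shock (3 rises of 10), hypoxia (3 rises and 1 fall of 14), cholesterol synthesis (2 rises and 4 falls of 21) and fatty acid oxidation (1 fall of 17) were not called by camera, with adjusted p = 0.130, 0.0863, 0.795, 0.795 and 0.866. For hypoxia the median log2 fold change was -0.03, while the mean was 0.11 and the test direction up. Leaving out 1 library gave 3 to 5 rises for senescence, 1 to 5 for hypoxia and for cholesterol synthesis, and 0 to 2 falls for fatty acid oxidation. Adjusted over the list alone their counts were 5 rises and 2 falls, 3 rises, 5 rises and 2 falls, 2 rises and 4 falls, and 0.

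Markers of other cells were measured with the same fits. Of 25 acinar markers 5 rose and 20 were not called, and 2 rose adjusted over the list alone (camera adjusted p = 2.8e-06, and adjusted p = 0.347 with an estimated correlation). These rises numbered 1 without PX 65, where Cpb1, Ctrb1 and Prss2 lost their calls, 3 without sham 47 and 2 without any 1 of sham 21, 22, 24, 50, 73 and 74 and PX 57, 58, 62 and 66; 0 rose with the PX animals of BG 121 or less or in the libraries of overlapping acinar scores. Prss3, a trypsinogen gene of a family with near-identical copies, had a mean of 944 ± 823 CPM in sham and 5411 ± 7214 CPM in PX, where PX 65 had 26295 CPM and the other 10 libraries averaged 3323 ± 2125 CPM (SD, n = 10). Of 14 duct markers 8 rose and 1 fell, as they did adjusted over the list alone, with Tspan8 rising 10.0-fold (camera adjusted p = 5.3e-04, and adjusted p = 0.135 with an estimated correlation). Of 17 mesenchymal markers 16 rose, and 16 adjusted over the list alone, with Col3a1 rising 7.56-fold (camera adjusted p = 4.2e-13, and adjusted p = 0.0985 with an estimated correlation). Of 11 endothelial markers 7 rose, and 8 adjusted over the list alone, with Tie1 rising 1.77-fold (camera adjusted p = 4.6e-04, and adjusted p = 0.178 with an estimated correlation). Endothelial rises numbered 2 with library totals only and 3 in the libraries of overlapping acinar scores. Alpha cell markers had 2 rises and 5 falls among 10 members, 2 and 6 adjusted over the list alone, with Fap at 2.33 ± 0.28 and Irx1 at -1.11 ± 0.29, and 3 falls without sham 73 or sham 74. Fap is also known from fibroblasts. Delta and PP cell markers had 2 falls of 7, Sst and Rbp4, and 2 adjusted over the list alone; camera called neither list (adjusted p = 0.377 and 0.204). With the macrophage and mesenchymal scores as covariates the acinar, duct and endothelial lists were not called (camera adjusted p = 0.324, 0.920 and 0.796), and the acinar list had a mean of -0.032 and a median of 0.066. Of the 27 lists tested, camera called 17 up and 2 down; of these 19 calls, 17 could be tested with both scores as covariates, where 0 were called in the same direction and 3 in the opposite one. With an estimated correlation camera called 0, with 10 at an unadjusted p under 0.05, and fry called 22. Lists of fewer than 5 measured members had no list test. In these, 4 of 4 lymphocyte, 3 of 3 red cell, 2 of 2 adipocyte and 2 of 4 Schwann cell markers rose, with the same counts adjusted over the list alone. The lists hold 16, 8, 9 and 9 markers, and the others were not measured. Of the 4 lymphocyte markers, 2 averaged at least 1 CPM in sham. A marker low in sham could pass the filter through its PX counts, so its rise is partly fixed by the filter. Without PX 44, 57, 58, 62 or 66 only 2 lymphocyte markers passed the filter, and these 2 rose. Without a filter 11 of 15 lymphocyte markers rose. Without sham 49, sham 50, PX 58, PX 62 or PX 65, 1 of 2 adipocyte markers rose.

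Over 13136 genes tested, edgeR's quasi-likelihood test called 4088 at a Benjamini-Hochberg adjusted p under 0.05, 1961 higher and 2127 lower in PX. Of these, 953 were at least 2-fold higher and 140 at least 2-fold lower. The lower calls numbered 1304 without sham 73, 1305 without sham 24, 1341 without sham 74, 1380 without sham 22 and 1378 without PX 41, so that higher calls were the majority there, and those at least 2-fold lower numbered 89 without sham 24. In each of these fits TMM scaled to sham 47, against PX 44 in the main setting, so scaling and library changed together. With DESeq2 size factors and all libraries kept, 1646 calls were lower and 2185 higher. Without PX 44, PX 65 and sham 46, which stood apart from their groups, 4835 genes were called and 3453 of the 4088 kept their call and direction; this set was chosen after seeing the data. The calls fell to 2198 with the acinar score as a covariate, to 2550 with the PX animals of BG 121 or less, to 902 in the 5 sham and 8 PX libraries of overlapping acinar scores and to 10 with the macrophage and mesenchymal scores as covariates, and rose to 6362 with limma voom quality weights. Of the 125 called named genes, 62 lost their call in the overlapping range, among them Pax6, Rfx6, Abcc8, Pdx1, Cacna1a, Cacna1d, Aldh1a3 and Txnip, and 1 reversed; of the 19 list calls 13 were kept there and that of the acinar list turned. The share of calls that were higher in PX was 47.97%, and 30.8% with library totals only, which moved the median of all genes to -0.28 on the log2 scale, 58.4% with the acinar covariate and 61.5% without the 20 most abundant genes in the totals. The called state of Ucn3 was lost in 12 of the 21 fits that left out 1 library (sham 21, 22, 49, 73 and 74 and PX 36, 37, 38, 41, 58, 62 and 65; adjusted p from 0.0502 to 0.104), that of Pdx1 without sham 21 (adjusted p = 0.0538) and that of Nkx6-1 without sham 22 (adjusted p = 0.0518); Nkx6-1 and Ucn3 were not called with the acinar covariate (edgeR, adjusted p = 0.116 and 0.164) or with the PX animals of BG 121 or less (adjusted p = 0.116 and 0.0959). Ucn3 was also not called with DESeq2 size factors, upper-quartile factors, surrogate variables or totals without the 20 most abundant genes (adjusted p = 0.0522, 0.0527, 0.0695 and 0.0732). Of the fits that lost Ucn3, those without sham 21, 22, 73 or 74 or PX 36, 37, 38 or 41 scaled to sham 47.

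In the authors' deposited table, which holds 13140 genes, 4073 had an adjusted p under 0.05, 1845 higher and 2228 lower. Of 13117 genes in both, 3820 were called in both the authors' deposited table and the edgeR fit, all 3820 in the same direction. The log2 fold changes of the authors' deposited table had a Pearson correlation of 0.989 with those of the edgeR fit across these genes, which are not independent replicates. The authors' deposited table gives log2 fold changes of -1.19 for Sst, 2.30 for Ldha and 5.77 for Mmp12. In the count table's coordinates, whose genome build is not given in the sources used here, Mmp12 runs from 5606592 to 5616493 on chromosome 8, Sst from 80358211 to 80359444 on chromosome 11 and Ldha from 102900286 to 102909707 on chromosome 1.

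Among the 11 PX animals, the slope of expression on the label BG asks whether genes follow glycemia within the operated group. No gene was called by edgeR among 14442 tested, with 1756 at an unadjusted p under 0.05; limma voom called 0 and DESeq2 called 27. The 3 genes of smallest p, chosen after their values were seen, were Gpd1 with a slope of 0.28 ± 0.04 log2 per 10 BG units, Cartpt with 0.44 ± 0.07 and Ppp1r1a with -0.27 ± 0.05 (SE, n = 11; edgeR, Benjamini-Hochberg adjusted p = 0.227, 0.230 and 0.235). DESeq2 called these 3 genes (adjusted p = 5.8e-04, 1.5e-04 and 7.4e-05). They were also called with a common slope over 21 animals (edgeR, adjusted p = 0.0121, 0.0121 and 0.0303). Without PX 65 the slopes of Gpd1, Cartpt and Ppp1r1a were 0.16, 0.47 and -0.17 (edgeR, adjusted p = 0.995 for each). Without PX 41 Gpd1 was called, with a slope of 0.33 (edgeR, adjusted p = 0.0198). Ins1 and Ins2 had slopes of 0.02 and 0.00, Sst of -0.02, Nkx6-1 of -0.19 and Txnip of 0.21 (adjusted p = 0.967, 0.999, 0.920, 0.364 and 0.395). Of 29 lists tested, camera called 8 with a positive direction, the disallowed, ChREBP target, respiratory chain, cell cycle, matrix, acinar, duct and macrophage lists, and 2 with a negative one, beta cell identity and secretion machinery. The smallest was that of respiratory chain subunits, at adjusted p = 1.9e-05, and adjusted p = 0.721 with an estimated correlation. Without the 2 animals farthest from the median BG camera called 1 list, respiratory chain subunits (adjusted p = 0.00293). With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05. Median and mean slope differed in sign for the heat shock, senescence, interferon and delta and PP lists, none of them called. The acinar list was among the 8, with a median slope of 0.27, 0 calls over all genes and 7 adjusted over the list alone. Across 13135 genes, which are not independent replicates, the slopes had a Pearson correlation of 0.537 and a Spearman correlation of 0.628 with the PX effects. Without the 2 animals farthest from the median BG the Pearson correlation was 0.181, and without PX 65 the genes at an unadjusted p under 0.05 numbered 394.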

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

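The tests of a lower endocrine share and of a wrong label on sham 46 alone were chosen after the results were seen, as was the comparison of sham 46 with the range of the PX libraries, and the covariates used for the disallowed genes were chosen after the data were seen. Among 172 measures, 38 had a sham library set far apart from the other 9 by the gap to its nearest neighbour; chance gives about 1 in 20 groups such a gap, and the 11 PX libraries were not tested. Sham 46 was the highest sham library in 19 of them. As mean log2 CPM, its list scores were 3.65 for disallowed genes, 5.11 for glycolysis, 7.52 for endoplasmic reticulum stress, 5.88 for matrix, 4.16 for antigen presentation, 5.34 for mesenchymal and 2.82 for macrophage genes, and its low score was 7.96 for beta cell identity. Its high genes, as log2 CPM, were Postn 3.50, Aldh1a3 4.63, Pdgfra 4.64, Vim 5.26, Dnajb11 7.15, Dnajc3 7.54, Mcm3 3.37, Mcm5 4.19, Col5a2 5.52, Col3a1 8.57, C7 7.30 and Csf1r 4.97. Its low genes were Cabp7 4.35, Unc5c 4.31, Cntn3 3.92, Casr 3.91, Syt12 2.79, Tenm4 5.02, Sst 8.74, Rfx6 6.65, Vegfa 8.45 and Slc7a2 9.35. Other libraries apart were sham 49 (secretion machinery 7.58 and Bag3 0.31, both low), sham 22 (senescence 3.88, high, and Pyy 1.91, low), sham 47 (Psmb8 0.50 and Ngfr 1.12, low), sham 74 (Il7r -1.89, low) and sham 50 (Cd37 -1.89, low).

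Sham 46 and PX 44 lay near the other group. On a score from the genes that separate the other libraries, 0 at the sham mean and 1 at the PX mean, PX 44 was at 0.339. This was above the other sham libraries (-0.09 to 0.11) and below the other PX libraries (0.633 to 1.40). Those libraries also chose the genes, so their ranges may be too narrow for a library left out, and the score cannot decide on a swap of the pair. PX 44 had a BG of 101, inside the sham range of 82 to 104. Its macrophage score of 3.02 lay above 1.955 in sham 21, the highest of the other sham libraries. Sham 46 was at 0.691, inside the PX range, but its BG of 97, macrophage score of 2.82 and Lgals3 level of 1.42 CPM lay below the lowest PX values of 101, 3.02 and 10.8. The values 101 and 3.02 were those of PX 44. Mitochondrial genes took 1.42% of the counts in sham 46, the lowest sham value, and 5.58% in PX 44, the highest PX value. The group means were 4.34% in sham and 2.91% in PX, so each library lay on the side of the other group. Of 515 genes that separate all PX from the other 9 sham libraries, sham 46 lay outside the PX range in 43.3%; on genes chosen again without the library in question, this was 86.6% to 97.7% for the other sham libraries, 0.775% to 33.3% for 10 PX libraries and 70.8% for PX 44. These values go both ways, between most PX and the other sham libraries. A wrong label on sham 46 alone may account for its place and stays open, as does a swap with PX 44. No biological explanation was tested.

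Macrophage and matrix genes were higher in PX. With the acinar score as a covariate the median log2 fold change of their 39 members was 2.21, against 2.42 without it, and 39 were called both times. This argues against a larger share of exocrine tissue of like make-up in both groups as the whole cause. The fit uses 1 acinar slope for both groups, so it cannot decide on exocrine tissue that differs between them. In the 5 sham and 8 PX libraries of overlapping acinar scores, 14 of 24 matrix genes rose and 0 fell. A lower share of endocrine cells would raise all other markers alike. However, the macrophage median of 2.74 exceeded the endothelial median of 0.50 by 2.24 (permutation of markers between the lists, p = 0.00222). This p is over marker genes, which are not independent replicates (estimated correlations 0.77 and 0.346), so it does not measure the spread between animals. Of the 15 macrophage markers, 14 had at least 1 CPM in sham and 0 were on another list. More macrophages and matrix-forming cells, or higher expression in them, remain as a hypothesis, and the operation itself and glycemia were not separated.

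Disallowed genes were higher in PX. With the macrophage and mesenchymal scores as covariates their median log2 fold change was -0.045 against 1.13 without, and called members went from 19 to 0. These scores explain most of the variance of group (R squared 0.769), and the macrophage scores of the groups do not overlap, so RNA from macrophages and mesenchymal cells cannot be told apart from a change in beta cells. Within PX the macrophage score and the mean of the disallowed genes had a Pearson r of 0.947 (permutation p = 2e-05) and a Spearman rho of 0.918 (p = 1.8e-04), with r = 0.925 without the 2 farthest animals. In sham r was 0.802 (p = 0.042), rho 0.442 (p = 0.204) and r -0.0188 without the 2 farthest, so the sham relation rests on those libraries.

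For the calls between groups, 1 of 100 splits of the 21 libraries, the real one, gave as many as 4088 genes, and the highest other gave 606. Likewise 1 of 100 gave as many as 1093 genes of at least 2-fold, with 302 the highest other, and 3 of 100 gave as many as 19 lists, with 19 the highest other. For both gene counts, a random assignment of single libraries to the groups can be excluded at 0.05. The splits treat all 21 libraries as exchangeable and break up the runs of animal numbers. Each run holds 1 group only, so differences between runs cannot be excluded as a source of these calls. The list count, at 3 of 100, passed the limit set beforehand only narrowly, as other splits also called 19 lists, so chance is not excluded for it. The other splits called a median of 7 lists while 96 of them called 0 genes by edgeR, so a camera call with the preset correlation is weak evidence.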

How the results depend on the processing

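Leaving out PX 44, PX 65 and sham 46, both marker scores as covariates and the libraries of overlapping acinar scores were chosen after seeing the data. Of 125 called named genes, 83 were tested and called under every alternative fixed before the data were examined. Another 2 (Il7r and Cd37) were called in those that tested them, 40 were lost in at least 1 and 0 reversed. When 1 library was left out, 15 were lost. Most named genes were picked by fold change or p in these same data, so these shares may overstate those of all calls. With the acinar covariate 2125 of all 4088 calls were kept in direction, and 96 of the 125 named genes. With PX animals of BG 121 or less these numbers were 2489 and 105. With both scores as covariates 0 of the 125 kept their call, 84 lost it without a change of direction and 41 reversed; in the overlapping acinar range 62 lost it and 1 reversed, and 13 of 19 list calls were kept. Called genes numbered 6362 with voom quality weights, 2198 with the acinar covariate, 2550 with PX animals of BG 121 or less, 902 in the overlapping acinar range and 10 with both scores as covariates. The genes changed at least 2-fold, PX against sham, numbered 2187 without a filter, 2062 with DESeq2, 655 in the overlapping range and 10 with both scores. Fewer libraries enter 2 of these settings; otherwise the cause was not tested. Leaving out 1 library gave 3292 to 4550 called genes (1709 to 2607 higher, 1304 to 2258 lower), 963 to 1308 of at least 2-fold (849 to 1165 higher, 89 to 155 lower), 18 to 19 lists and 0 to 1 BG slopes. The share of calls higher in PX was 47.4% to 60.4%; TMM scaled to PX 44 in the main setting, and fits that scaled to sham 47 gave 55.2% or more.

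Lists called numbered 3 with both scores, each opposite to its direction without them, and 0 with an estimated correlation. BG slopes called numbered 6 without a filter, 1 with the acinar covariate, 27 with DESeq2 and 4 with a common slope over 21 animals; slope lists numbered 0 with an estimated correlation and 1 without the 2 farthest animals. The correlation of slope and PX effect was 0.663 over called genes and 0.181 without the 2 farthest animals. The cause was not tested.

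With both scores as covariates, which take up most of the group difference (R squared 0.769), log2 fold changes reversed for Cabp7 (0.18), Unc5c (0.35), Cntn3 (0.36), Syt12 (0.39), Nkx6-1 (0.064), Ucn3 (0.26), Rfx6 (0.30), Rims2 (0.021), Vegfa (0.27), Slc7a2 (0.10), Ldha (-0.73), Txnip (-0.29), Hk2 (-0.033), Pdgfra (-0.23), Cd24 (-0.44), Pfkfb3 (-1.13), Pgk1 (-0.46), Bhlhe40 (-0.19), Tkt (-0.17), Hmgcs1 (-0.0044), Ndufv2 (-0.27), Sdhb (-0.16), Atf3 (-0.58), Gpx1 (-0.54), Slc7a11 (-0.23), Slc2a1 (-0.10), Jun (-0.22), Ier3 (-0.33), Hspb8 (-0.26), Hspb1 (-0.59), Cdkn1a (-0.33), Psmb8 (-0.50), Psmb9 (-0.42), Prss2 (-0.080), Ctrb1 (-0.75), Car2 (-0.20), Lck (-0.052), Hba-a2 (-0.10), Hbb (-0.55), Fabp4 (-0.25) and Lipe (-0.42). Among lists called in either fit, the camera direction reversed for those that follow, with list means in brackets. They were beta_identity (0.34), secretion_machinery (0.023), beta_disallowed (-0.10), glycolysis (-0.33), oxphos (-0.25), antioxidant (-0.078), immediate_early (-0.24) and interferon (-0.23). The mean of the acinar list also changed sign, as given above. In the overlapping acinar range Cpb1 (-0.062) and the m_acinar list (-0.36) reversed, where the libraries were chosen for like acinar scores.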

Other observations

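The clock list was written after Per3, and the cilium list after Dnah2, Dnah12, Rgs22 and Ccdc187, were seen to fall. The lists were tested without these genes, but the cilium list holds other dynein genes, Dnah9 and Dnah11 among them. Of 15 measured clock genes besides Per3, 7 fell, 0 rose and 8 were not called, with a median log2 fold change of -0.33. Nr1d1 and Nr1d2, repressors of the clock, fell by 1.08 ± 0.36 and 0.98 ± 0.25 on the log2 scale, Dbp fell by 0.94 ± 0.25 and Per1 fell by 0.57 ± 0.14, while Arntl had -0.01 ± 0.15 (edgeR, SE). The camera p was 0.00753, adjusted p = 0.0151 over both lists, and p = 0.0634 with an estimated correlation. A hypothesis is that clock genes shifted together between groups, which may also reflect the hour of collection, which was not tested. The macrophage, mesenchymal and acinar scores were also higher in PX. Neither the clock list nor the cilium list was fitted with these scores as covariates. Of 16 cilium genes 6 fell, and Rfx3 fell by 0.79 ± 0.13 and Dnah9 fell by 0.91 ± 0.18, and 10 were not called; camera gave p = 0.0519 (p = 0.145 with an estimated correlation), so a fall of the group did not pass.

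Among the 11 PX animals, 5 relations of BG with library scores were computed. The highest Pearson correlation was with principal component 1, r = 0.585 (permutation p = 0.0577, adjusted p = 0.288) and Spearman rho 0.575 (p = 0.0676, adjusted p = 0.169), and r = 0.268 without the 2 farthest animals. The highest Spearman correlation was with the macrophage score, rho 0.584 (p = 0.0621, adjusted p = 0.169), with r = 0.327 (p = 0.327, adjusted p = 0.409) and r = 0.112 without the 2 farthest animals. Of 100 orders of BG, the real one included, 19 gave at least the observed 1756 genes at an unadjusted p under 0.05, with 4236 the highest other, and 21 gave a correlation of slope and PX effect of at least 0.537 in size, with 0.701 the highest other. Chance orders of BG were therefore not excluded for either result.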
